A study of Homo sapiens with 30 samples.

How the data were processed

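Gene expression was measured in 30 libraries of human microglia derived from a commercial induced pluripotent stem cell line. The 6 groups were WT and PILRA knockout cells, each untreated, with LPS or with IFNg for 24 h, with 5 libraries per group. Per the labels, the experiment was repeated on 5 days (59, 63, 70, 73 and 77 days in vitro), each holding all 6 groups, and the libraries were QuantSeq FWD 3′ libraries with molecular identifiers. The authors name STAR 2.7.9a, Salmon 1.10.1, R 4.1.1, edgeR 4.0.12 and GRCh38, with no role or order, and do not state the annotation release. The deposited count table is in expected_counts, estimated counts per gene that were all rounded to 2 significant digits, which makes a single value wrong by up to 5%. Library totals deposited with the samples are also expected_counts, and the table sums lay within 0.2% of them. Of positive counts under 10, 15.2% were not whole. The authors' normalized table is named signal here: CPM of a library size times a factor of 0.913 to 1.11 (geometric mean 1), again in 2 digits, with column sums of 0.901 to 1.1 M. RNA integrity is a score per the file headers, from 9 to 10, with 1 value missing.

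Counts were rounded to whole numbers and fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (minimum count 10), which left 13886 of 62750 genes and 99.47% of counts. TMM factors differed from the authors' factors by at most 5.5%. A quasi-likelihood F test (two-sided) was run with group and day as terms, which left 20 residual degrees of freedom, and the biological coefficient of variation was 11.8%. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The 11 comparisons were LPS and IFNg against untreated in each genotype, KO against WT in each treatment and averaged, LPS against IFNg in WT, and the difference of each response between genotypes. PILRA was also tested by exact permutation of its log2 CPM, which ignores the day. Median depth was 5.57 M counts. Changes were simulated in 200 genes with a mean of at least 10 CPM over the groups, without day effects. Genes of lower level were not tried. There the test recovered 82.1% of 1.5-fold and 100% of 2-fold changes between untreated KO and WT, with 10 false calls. For the difference of the LPS response it recovered 58.2% at 1.5-fold, 88.1% at 2-fold and 100% at 4-fold, with 8 false calls.

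Before the data were examined, the comparisons, the tests, the alternatives, the rule for named genes and 34 gene lists were fixed. The pathway lists were NF-kB cytokines and chemokines, NF-kB feedback, type I interferon, IFNg, MHC class I, MHC class II, homeostatic microglia, disease-associated microglia, cholesterol synthesis, LXR targets, fatty acid oxidation, lipid droplets, OXPHOS, glycolysis and hypoxia, lysosome, migration, ITIM and paired receptors, PILRA neighbours, proliferation, complement, stress response, scavenger receptors and oxidative defence. Marker lists covered astrocyte, pluripotent, blood progenitor, erythroid, megakaryocyte, mast cell, granulocyte precursor, monocyte, fibroblast, endothelial and neuron. The 26 lists with 5 or more tested genes gave 286 tests with camera of limma 3.58.1 (preset correlation 0.01), which asks whether a list moves more than other genes. Adjusted p-values cover all 286 tests. They were repeated with an estimated correlation and with fry, which asks whether a list moves on balance in a single direction and does not compare it with other genes. Camera passed 134 tests, 46 with an estimated correlation. Response lists were the 200 genes with the largest rise or fall in the mean response of both genotypes.

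Named genes were PILRA and PILRB, the 8 largest rises and 8 largest falls per comparison, and up to 4 members of each list with the smallest p. The largest changes had to pass, to go the same way on all 5 days, to reach a mean of 10 CPM in a group compared and to have a gene symbol that is not a clone name. Genes on the Y chromosome, XIST and, chosen after values were seen, genes whose presence differs between haplotypes were left out of the named genes, as were 47 duplicate entries of the pseudoautosomal region. Coordinates are from GENCODE 29 on GRCh38. Days were checked as pairs: residuals of libraries from the same day correlated at a mean of 0.087, against −0.021 for other days, and 18 of 30 libraries correlated best with their own day. Replicates correlated at 0.9518 to 0.9842.

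Alternatives were RLE size factors, DESeq2 1.42.0, limma-trend on the authors' values, no filter on low counts, no day block, fits with only the groups compared, response lists of 100 and 500 genes, and fits without each day and each library. Chosen after seeing the data were counts redrawn within their rounding and fits without the untreated KO library of day 73, alone or with the WT library with LPS of day 70, and without the untreated WT library of day 63, alone or with the untreated KO library of day 73. Clone effects are not analysed here, since the number of clones per genotype and the relation of the KO cells to WT are not given in the sources used here.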

Results

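Messenger RNA was counted by 3′ tag sequencing in human microglia grown from a commercial induced pluripotent stem cell line, in wild-type (WT) cells and in cells carrying a PILRA knockout (KO). PILRA encodes an inhibitory receptor of myeloid cells that signals through ITIM motifs. Each genotype was left untreated or was given lipopolysaccharide (LPS), the bacterial ligand of Toll-like receptor 4, or interferon gamma (IFNg), a cytokine that activates macrophages, for 24 h. IFNg was given at 1 ng/ml. LPS is stated as 10 ng/ml in the sample labels and as 100 ng/ml in the protocol, and which dose was used is not given in the sources used here. The 6 groups hold 5 libraries each, made on 5 days at 59, 63, 70, 73 and 77 days in vitro. Library totals ran from 3.86 to 6.86 M (mega) counts, with a median of 5.57 M. Group means were 4.75 ± 0.58 M (SD, n = 5) in untreated WT, 5.48 ± 0.69 in WT with LPS and 5.40 ± 0.28 in WT with IFNg. The KO means were 5.76 ± 0.72, 5.94 ± 0.75 and 6.09 ± 0.39 M in the same order. Mitochondrial transcripts took 16%, 13.6% and 14.9% of counts in WT and 9.86%, 10.7% and 10.2% in KO. Gene levels below are mean CPM (counts per M counts) ± SD over n = 5 libraries, and fold changes are on the log2 scale ± SE. Replicates are repeats on different days with freshly seeded cells, and the number of clones per genotype is not given in the sources used here. The adjusted p-values measure the spread between replicate libraries that is left once the day term is fitted. Whether that holds any spread between clones is not known.

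PILRA itself (ENSG00000085514, chromosome 7, bases 100367530 to 100400099 of GRCh38, plus strand) was read first in every library. In untreated WT cells it stood at 78.0, 70.8, 66.9, 94.5 and 118 CPM on the 5 days, and in untreated KO cells at 5.75, 5.30, 5.87, 2.98 and 6.34 CPM. With LPS the WT libraries gave 173, 169, 98.2, 116 and 174 CPM and the KO libraries 7.34, 9.47, 7.97, 7.12 and 9.90 CPM. With IFNg the WT values were 97.8, 89.7, 68.7, 104 and 133 CPM and the KO values 7.86, 6.55, 6.91, 5.64 and 4.37 CPM. KO cells kept 6.12% of the WT level untreated, 5.72% with LPS and 6.34% with IFNg. Each of these 3 differences had a two-sided exact permutation p of 0.0079, the smallest that 5 against 5 libraries can give when the day is ignored. Exchanges of the labels within the 5 days alone could not reach a p under 0.05. Averaged over treatments PILRA was lower, at −4.03 ± 0.10 in KO (adjusted p = 2.90e-22). This averaged test counts the 3 libraries of a genotype on a day as separate replicates. LPS raised the transcript by 0.77 ± 0.14 in WT (adjusted p = 3.29e-05) and by 0.70 ± 0.22 in KO (adjusted p = 0.024). The KO rise did not pass without day 63, without day 73 or without the day block. IFNg gave no change that passed, at 0.20 in WT (adjusted p = 0.331) and 0.30 in KO (adjusted p = 0.452). The edited part of the gene is not given in the sources used here, so a 3′ tag that lies outside a deleted part would check nothing about the edit. The neighbouring paralog PILRB, which encodes the activating partner receptor, gave count sums of 31.6 over the WT libraries and 61 over the KO libraries, too few to test.

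**Figure D1:**
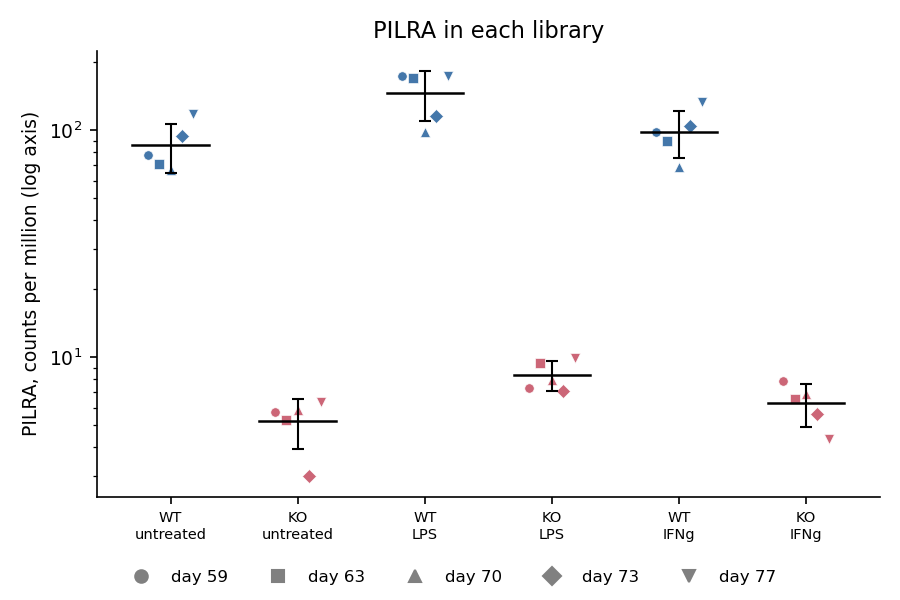
PILRA level in CPM on a log axis for each of the 30 libraries in the 6 groups, WT in blue and KO in red, with marker shape for the day, a line at the group mean and bars of ± SD. The lowest WT library stands at 66.9 CPM and the highest KO library at 9.90 CPM.

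LPS in WT cells asks what a bacterial signal does to these microglia over 24 h. NF-kB and glycolysis genes rose. Gene by gene, interferon genes also rose and homeostatic microglial genes fell, but these lists did not hold with an estimated correlation. IL12B, which encodes the shared subunit of interleukins 12 and 23, rose by 7.30 ± 0.24, from 0.551 ± 0.27 to 96.3 ± 49 CPM. ACOD1, whose enzyme makes itaconate, rose by 8.17 ± 0.42, to 66.7 ± 15 CPM, and the tryptophan-degrading enzyme gene IDO1 rose by 6.87 ± 0.51, to 212 ± 110 CPM. The other large rises were MT1M (7.71), ADORA2A (7.33), CCL15 (7.27), TNFAIP6 (6.85) and ISG20 (6.71). Among NF-kB cytokines and chemokines 22 of 24 rose and 1 fell, with CCL5 up 5.92 to 708 ± 120 CPM and CXCL1 up 5.11. All 22 NF-kB feedback genes rose, including TNFAIP3 (4.43), NFKBIA (2.73) and TRAF1 (5.18), whose products restrain or tune the pathway. All 31 type I interferon genes rose, among them RSAD2 (5.79), USP18 (4.39) and the RNA sensor gene IFIH1 (2.94). Of the IFNg genes 27 of 29 rose, such as APOL3 (5.63) and GBP1 (4.70), and of the MHC class I genes 16 of 18, such as PSME2 (2.50) and TAP2 (2.39). MHC class II genes split, with HLA-DMB down by 1.54 and CTSS up by 0.33 among 3 that rose and 2 that fell. Growth factor gene IGF1 fell by 3.36 ± 0.17, from 129 ± 21 to 12.5 ± 2.9 CPM, and FABP4 (−3.82), PITPNM3 (−3.68), RASL11B (−3.55), ZNF704 (−3.45), S1PR1 (−3.33), CD180 (−3.22) and ADAMTS15 (−3.20) fell as well. Homeostatic microglial genes went down in 15 of 19 cases, with GPR34 at −3.12 and MEF2C at −1.71, and 11 of 20 disease-associated genes fell, with CD9 at −2.93 and the lipid receptor gene TREM2 at −1.80. Glycolysis and hypoxia genes rose in 24 of 26 cases, with ADM at 3.78 and LDHA at 1.34, while 44 of 72 OXPHOS genes fell. Fatty acid oxidation genes fell in 18 of 26 cases, with CD36 at −2.16, whereas ACSL1 rose by 3.03. Counts adjusted over the list alone differed by at most 2 genes in these lists.

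The LPS response in WT took in 6314 of 13886 tested genes (45.5%), 3052 higher and 3262 lower, and 869 rose and 986 fell by 2-fold or more. Of 26 lists 14 passed camera with its preset correlation, and 5 kept their call with an estimated correlation. Those 5 were both NF-kB lists (adjusted p = 3.22e-19 and 9.75e-23, and adjusted p = 0.00446 and 0.00158 with an estimated correlation), MHC class I (adjusted p = 3.53e-13, and 0.0292), fatty acid oxidation (adjusted p = 0.000262, and 0.0285) and glycolysis (adjusted p = 1.77e-11, and 0.0314). Type I interferon genes passed at adjusted p = 8.35e-21 but had adjusted p = 0.153 with an estimated correlation, and the IFNg genes went from 2.03e-16 to adjusted p = 0.123 with an estimated correlation. Homeostatic genes had adjusted p = 6.48e-07, and adjusted p = 0.0932 with an estimated correlation. The type I interferon rise was uneven between days: CXCL10 stood at 1640 CPM in the WT library with LPS of day 70 and at 112 to 441 CPM in the other 4. Reads of metallothionein, GBP and HLA paralogs can be assigned to one another, which leaves single members such as MT1M uncertain.

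IFNg in WT cells asks which genes the macrophage-activating cytokine controls in the same microglia. IFNg genes and MHC class I and II genes rose. The T-cell chemokine gene CXCL9 rose by 5.95 ± 0.33, from 3.93 ± 0.91 to 251 ± 110 CPM, and GBP1 by 5.06 ± 0.28, to 809 ± 330 CPM. GBP4 (5.72), GBP5 (5.34), IDO1 (5.33), SECTM1 (5.26), ETV7 (5.09) and PLAAT4 (5.01) were the other large rises. Of the IFNg genes 28 of 29 rose, including GBP2 (4.25), APOL1 (4.53), SERPING1 (3.34) and WARS1 (3.05). All 18 MHC class I genes rose, with the immunoproteasome gene PSMB9 at 3.88 and PSME2 at 3.03. All 14 MHC class II genes rose as well, with HLA-DQB1 at 3.48, HLA-DMB at 1.69 and HLA-DPA1 at 1.67. Type I interferon genes rose in 21 of 31 cases, 22 adjusted over the list alone, with STAT2 at 1.74 and IFIT3 at 2.21. NF-kB cytokines and chemokines rose in 9 of 24 cases, with CCL7 at 2.72 and TNF at 1.84, and 13 of 22 feedback genes rose, with CD40 at 2.26. ITIM and paired receptor genes rose in 18 of 34 cases, 20 adjusted over the list alone, with LILRB3 at 1.49 and PTPN6 at 0.82. Complement genes rose in 10 of 20 cases, with C1QB at 1.25. The hyaluronan receptor gene LYVE1 fell by 3.12 ± 0.42, from 53 ± 24 to 6.50 ± 2.7 CPM, and S1PR1 (−2.73), PITPNM3 (−2.19), LYPD1 (−1.85), CDK1 (−1.78), CRABP2 (−1.71), SLC18B1 (−1.66) and KCNJ1 (−1.58) also fell. LXR targets fell in 6 of 14 cases, among them the cholesterol exporter gene ABCA1 at −0.96 and APOE at −0.55. Where not given, counts adjusted over the list alone differed by at most 1 gene.

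IFNg changed 3151 genes in WT (22.7% of those tested), 1636 higher and 1515 lower, with 377 up and 238 down by 2-fold or more. Of 26 lists 11 passed camera, and 4 held with an estimated correlation: the IFNg genes (adjusted p = 1.11e-47, and 0.00552 with an estimated correlation), MHC class I (7.32e-36, and 0.00119), MHC class II (3.39e-22, and 0.00119) and NF-kB feedback (1.05e-08, and 0.0337). The type I interferon list had adjusted p = 1.01e-12, and adjusted p = 0.285 with an estimated correlation. For the ITIM list the values were adjusted p = 4.75e-07, and adjusted p = 0.154 with an estimated correlation. In the homeostatic list the median was −0.10 and the mean 0.04, and camera leaned down without passing (adjusted p = 0.473).

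A direct comparison of LPS with IFNg in WT cells asks which parts of activation belong to each stimulus. NF-kB genes were higher with LPS, and MHC class II genes were higher with IFNg. Gene by gene, type I interferon genes were also higher with LPS, but the list did not hold with an estimated correlation. IL12B stood at 96.3 ± 49 CPM with LPS and 0.631 ± 0.32 with IFNg, a difference of 7.13 ± 0.23, and ADORA2A (7.79), TNIP3 (6.52), PTGES (6.17), CLEC4E (6.01), TMEM171 (5.54), ACOD1 (5.45) and TNFAIP6 (5.39) were also higher with LPS. CIITA, the class II transactivator gene, stood at 3.37 ± 1.1 CPM with LPS and 51.1 ± 14 with IFNg, a difference of −3.93 ± 0.25. PLAAT4 (−5.22), APOL4 (−4.30), FFAR4 (−4.00), SLC15A2 (−3.69), IL18BP (−3.46), DKK2 (−3.33) and HLA-DQB1 (−3.24) were lower with LPS. NF-kB cytokines were higher with LPS in 23 of 24 cases, feedback genes in 21 of 22 and type I interferon genes in 28 of 31, with USP18 at 4.70 and MX2 at 3.08. MHC class II genes were lower with LPS in 13 of 14 cases, with HLA-DMB at −3.23, homeostatic genes in 15 of 19 and OXPHOS genes in 48 of 72. Glycolysis genes were higher in 18 of 26 cases, with HIF1A at 1.56 and PFKFB3 at 2.12. Scavenger receptor genes were lower in 13 of 20 cases, among them CD36 (−1.49) and MSR1 (−0.96). Adjusting over the list alone moved these counts by at most 3 genes. In total 5303 genes differed, 2521 higher and 2782 lower with LPS. Of 14 lists that passed camera, 6 held with an estimated correlation: both NF-kB lists (adjusted p = 0.00426 and 0.00231), MHC class II (0.00548), disease-associated genes (0.0267), fatty acid oxidation (0.0145) and lysosome (0.049). For type I interferon genes the list had adjusted p = 9.09e-14 in the preset test and adjusted p = 0.264 with an estimated correlation.

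LPS in KO cells asks whether microglia without PILRA still answer the bacterial signal. They did, with rises in monocyte markers and NF-kB cytokines and chemokines. S100A8, which encodes a calcium-binding alarmin of monocytes and neutrophils, rose by 4.95 ± 0.39, from 14.8 ± 6.4 to 460 ± 130 CPM. TNIP3 (4.61), CCL1 (4.35), CLEC4E (4.20), CXCL1 (3.78), PTGES (3.68), HLA-DQA2 (3.61) and FAM177B (3.38) were the next largest rises. All 7 monocyte markers rose, including S100A9 (2.17), VCAN (3.15) and S100A12 (4.8). NF-kB cytokines rose in 19 of 24 cases, with CCL5 at 3.12, CCL4 at 2.50 and CCL3 at 1.85, and 20 of 22 feedback genes rose, with SOD2 at 2.94, TNFAIP3 at 2.27 and NFKBIA at 1.65. Only 3 of 31 type I interferon genes rose, IFI27 (1.44), OAS1 (0.71) and OAS3 (0.89), and 1 adjusted over the list alone. This count depended on a single library, untreated KO of day 73, which had raised interferon genes: without it 24 of 31 rose, with a list median of 1.18 in place of 0.43. Leaving out untreated WT of day 63 instead gave 5 of 31, and leaving out both gave 25. Of the IFNg genes 4 of 29 rose, such as ANKRD22 (2.28), and 8 rose without that library. MHC class I genes rose in 5 of 18 cases and fell in 1, with TAPBP at 0.51. FABP4 fell by 2.32 ± 0.31, to 14.1 ± 8.3 CPM, and NCAPH (−2.11), CYSLTR1 (−2.06), NMRK2 (−2.02), FGL2 (−2.0), CD300LB (−1.99), ZNF704 (−1.98) and SCIN (−1.94) fell too. Disease-associated genes fell in 14 of 20 cases, with TREM2 at −1.01 and GPNMB at −0.66, homeostatic genes in 11 of 19, with GPR34 at −0.98, and lysosome genes in 16 of 33, with LIPA at −0.86 and NPC2 at −0.64. Oxidative defence genes rose in 12 of 22 cases, with NCF1 at 2.02, and glycolysis genes in 15 of 26, with LDHA at 0.94. The other counts moved by at most 2 genes when adjusted over the list alone.

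In KO cells LPS changed 2892 genes (20.8%), 1398 higher and 1494 lower, with 311 up and 265 down by 2-fold or more. Of 14 lists that passed camera, 6 held with an estimated correlation: both NF-kB lists (adjusted p = 0.00426 and 0.00119), monocyte markers (0.00535), disease-associated genes (0.00552), fatty acid oxidation (0.0105) and lysosome (0.018). Type I interferon as a list passed at adjusted p = 1.04e-05, and had adjusted p = 0.522 with an estimated correlation. Homeostatic genes had adjusted p = 0.000183, and adjusted p = 0.215 with an estimated correlation.

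IFNg in KO cells asks the same of the cytokine signal. IFNg genes and MHC class I genes rose, and proliferation genes fell. GBP5 rose by 5.79 ± 0.44, to 130 ± 70 CPM, and CXCL9 by 5.78 ± 0.33, from 3.15 ± 0.69 to 172 ± 40 CPM. GBP4 (5.29), GBP2 (4.52), SECTM1 (4.43), PLAAT4 (4.30), IDO1 (4.30) and GBP1 (4.17) followed. Of the IFNg genes 28 of 29 rose, and all 18 MHC class I genes rose, with PSME2 at 2.18, TAP2 at 2.04 and PSMB9 at 3.02. MHC class II genes rose in 12 of 14 cases, with HLA-DRA at 2.05, HLA-DPA1 at 1.51 and CD74 at 0.79. Type I interferon genes rose in 21 of 31 cases, with STAT2 at 1.30, and in 28 of 31 without untreated KO of day 73. Complement genes rose in 10 of 20 cases, with SERPING1 at 3.69 and C1QB at 1.69, and oxidative defence genes in 12 of 22, with PRDX1 at 0.48. The integrin gene ITGB7 rose by 2.08. LYVE1 fell by 3.40 ± 0.46, from 37 ± 22 to 3.48 ± 3.3 CPM, NMRK2 by 2.20 and THBD by 1.94. Proliferation genes fell in 18 of 25 cases, 21 adjusted over the list alone, with RRM2 (−2.36), TYMS (−2.11), PCLAF (−1.97), ASPM (−1.91), MKI67 (−1.69), CDK1 (−1.69) and TOP2A (−1.52). Adjusted over the list alone, the other counts moved by at most 1 gene. IFNg changed 2211 genes in KO (15.9%), 1195 higher and 1016 lower, and 1396 with day 63 left out. Of 11 lists that passed camera, 4 held with an estimated correlation: the IFNg genes (adjusted p = 0.00446), MHC class I (0.00119), MHC class II (0.00231) and proliferation (0.0155). As a list, type I interferon genes had adjusted p = 4.33e-16 in the preset test and adjusted p = 0.215 with an estimated correlation.

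**Figure D2:**
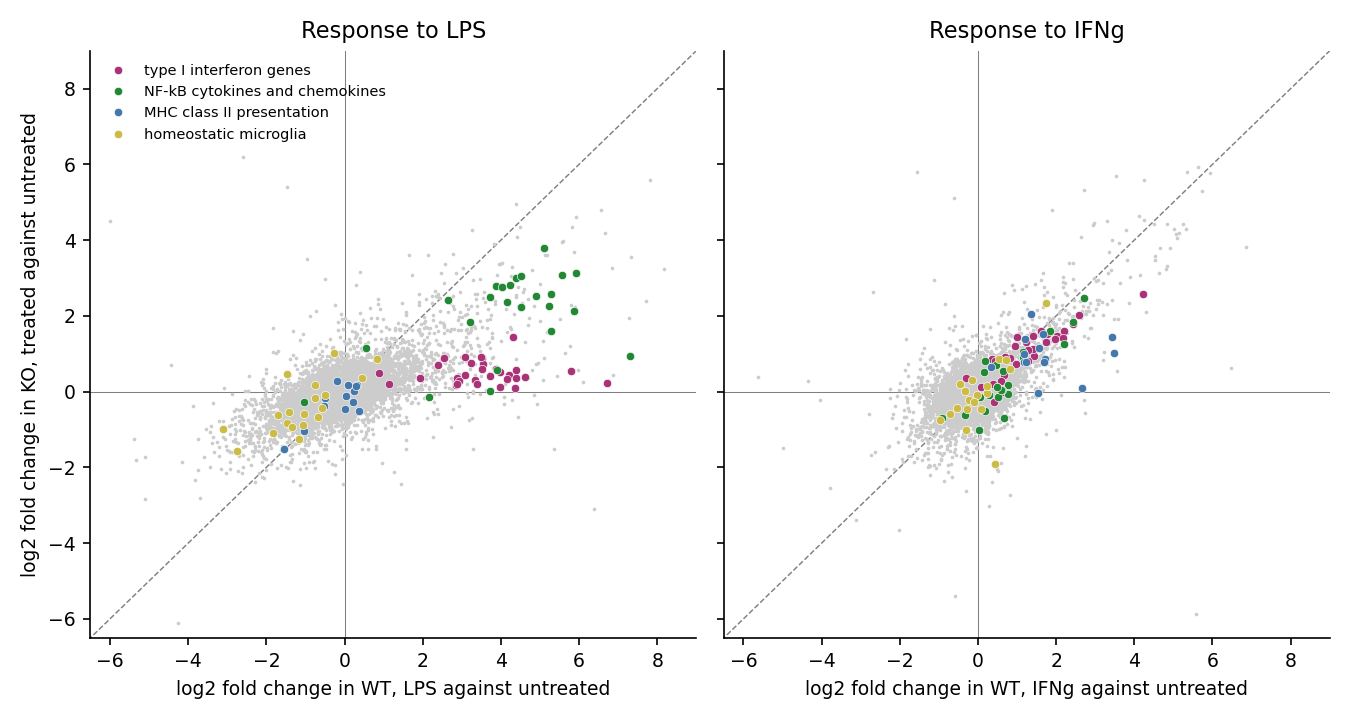
Log2 fold change of each tested gene with LPS or IFNg, in WT on the horizontal axis and in KO on the vertical axis, in grey, with type I interferon genes, NF-kB cytokines, MHC class II and homeostatic genes in colour and a dashed line of equal response. Type I interferon genes lie far under the line with LPS, at list medians of 3.51 in WT and 0.43 in KO (1.18 without untreated KO of day 73), and with IFNg at 1.28 and 1.12 (1.72).

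Untreated KO cells set against untreated WT cells ask what the loss of PILRA, or anything else that parts the 2 genotypes, does at rest. MHC class II genes were lower in KO, and cholesterol synthesis genes were higher. CCL18 (ENSG00000275385, chromosome 17, bases 36064280 to 36072032), a chemokine gene of alternatively activated macrophages, was lower, at −6.36 ± 0.13, with 1.90 ± 0.14 CPM in KO and 158 ± 26 in WT. HLA-DRA (ENSG00000204287, chromosome 6, bases 32439842 to 32445046) was lower, at −5.55 ± 0.15, with 15 ± 2.3 against 702 ± 65 CPM. MHC class II genes were lower in 12 of 14 cases and higher in 1, with HLA-DRB1 at −5.18 and HLA-DPA1 at −4.46. TRIM4 (−6.36), CEBPZOS (−5.65), NLRP2 (−5.49) and PSMD5 (−4.98) were also near 0 in KO. GPNMB (ENSG00000136235, chromosome 7, bases 23235967 to 23275108), which encodes a glycoprotein of lipid-loaded microglia, was lower, at −3.58 ± 0.07, with 93.5 ± 9.5 against 1110 ± 84 CPM. Other disease-associated genes were mixed, 6 higher and 10 lower, with CHI3L1 at 1.55 and CD68 at −1.82. The largest rises were HSPB7 (3.82), FCRLA (3.69), NMRK2 (3.63), PARM1 (3.48), GAL (3.37), COL11A2 (3.32), PRSS22 (3.26) and MYH14 (3.24). Cholesterol synthesis genes were higher in 22 of 25 cases, 24 adjusted over the list alone, with MSMO1 at 2.08, CYP51A1 at 1.59 and FDFT1 at 1.36. The sterol exporter genes ABCA1 (−1.53) and ABCG1 (−2.33) were lower, in an LXR target list of 4 higher and 4 lower whose median was 0.06 and mean −0.12. Complement genes were lower in 13 of 20 cases, with C2 at −1.92, C1QB at −1.73 and C1QA at −1.49, and lysosome genes in 19 of 33, with CTSK at −1.18. Among ITIM and paired receptor genes 11 of 34 were lower, 14 adjusted over the list alone, with LILRB4 at −4.58, LILRB1 at −3.12 and FCGR2A at −1.63. Migration genes went both ways, with FPR3 at −4.58 and MMP9 at 2.06. Glycolysis genes were higher in 16 of 26 cases, with NDRG1 at 1.84, and proliferation genes in 14 of 25, with AURKA at 1.55. Lipid droplet genes had 3 higher and 3 lower, DGAT2 at 2.74 and PLIN2 at −1.0. The remaining counts moved by at most 2 genes when adjusted over the list alone.

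Between untreated KO and WT cells 4950 genes differed (35.6%), 2436 higher and 2514 lower. Of 13 lists that passed camera, 4 held with an estimated correlation: MHC class II (adjusted p = 1.19e-13, and 0.00446 with an estimated correlation), cholesterol synthesis (2.19e-15, and 0.00552), lysosome (5.71e-05, and 0.0341) and fibroblast markers (3.15e-06, and 0.00535). Complement genes had adjusted p = 1.72e-05, and adjusted p = 0.124 with an estimated correlation. Fibroblast or mesenchymal markers were lower in 6 of 8 cases, with ACTA2 at 1.61 ± 0.24 against 29.4 ± 3.8 CPM and COL1A1 at 1.80 ± 0.54 against 11.3 ± 5.9. Mitochondrial transcripts took 9.86% of counts in untreated KO against 16% in untreated WT, and among nuclear OXPHOS genes 20 of 72 were higher and 8 lower (adjusted p = 0.043, and adjusted p = 0.645 with an estimated correlation). Type I interferon genes were lower in 5 of 31 cases with a median of −0.27, and in 22 with a median of −1.09 without untreated KO of day 73. Untreated WT of day 63 was raised as well, with a list mean of 4.94 against 3.66 to 4.43 in the other untreated WT libraries. Without it 3 of 31 were lower, with a median of −0.18, and without both libraries 16, with a median of −0.88. The 16 tested PILRA neighbours on chromosome 7 had 1 higher and 3 lower, with a median of −0.10. Genotype and clone cannot be told apart here, because the clones behind each genotype are not given in the sources used here.

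With LPS, KO against WT asks how the genotypes differ in the inflamed state. The WT NF-kB genes were far above those of KO, on top of the differences seen at rest. Gene by gene, the WT interferon genes were far above those of KO as well. With LPS the type I interferon list mean ran from 7.04 to 8.29 log2 CPM in WT and from 3.76 to 4.73 in KO. Set against other genes by camera, however, the interferon lists did not hold with an estimated correlation. IL12B was lower, at −7.08 ± 0.22, with 0.690 ± 0.46 CPM in KO against 96.3 ± 49 in WT, and IDO1 at −6.30 ± 0.46, with 2.65 ± 0.86 against 212 ± 110. CCL18 (−6.46), CXCL11 (−6.28), APOBEC3A (−6.05), the lymph-node homing receptor gene CCR7 (−5.87), RSAD2 (−5.78) and HLA-DRA (−5.72) were also among the largest falls. All 31 type I interferon genes were lower in KO, with OAS3 at −3.91 and IFIH1 at −2.83, and 27 of 29 IFNg genes, with GBP1 at −3.82. NF-kB cytokines were lower in 20 of 24 cases, with CCL8 at −4.82, CXCL6 at −3.18 and CCL4 at −2.15, and 20 of 22 feedback genes, with TNFAIP6 at −3.77 and TNFAIP3 at −1.82. MHC class II genes were lower in 13 of 14 cases and MHC class I genes in 15 of 18, with HLA-E at −1.36. LILRB4 (−5.54), LILRB1 (−5.33), FPR1 (−4.42), C1S (−3.22) and CFB (−2.57) were lower as well. FCRLA (4.08), HSPB7 (4.05), PTPN13 (3.76), CDA (3.66), PARM1 (3.60) and SLC30A3 (3.27) were higher in KO. Cholesterol synthesis genes were higher in 22 of 25 cases, with CYP51A1 at 1.97. OXPHOS genes were higher in 45 of 72 cases, where mitochondrial transcripts took 10.7% of KO and 13.6% of WT counts, and proliferation genes in 18 of 25, with TOP2A at 1.61. Monocyte markers were higher in 6 of 7 cases, with FCN1 at 2.16 and S100A8 at 1.33. Fibroblast markers were lower in 7 of 8 cases, with ACTA2 at −3.71. Counts adjusted over the list alone differed by at most 2 genes. In all 6298 genes differed (45.4%), 3181 higher and 3117 lower. Of 14 lists that passed camera, 5 held with an estimated correlation: both NF-kB lists (adjusted p = 0.0322 and 0.0105), MHC class II (0.00533), cholesterol synthesis (0.00935) and fibroblast markers (0.00787). The type I interferon list had adjusted p = 8.05e-21 in the preset test and adjusted p = 0.153 with an estimated correlation. For the MHC class I list these were adjusted p = 2.43e-10, and adjusted p = 0.0582 with an estimated correlation.

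With IFNg, the genotype comparison asks whether the cytokine removes or widens the difference in antigen presentation. Class II genes stayed far lower in KO. HLA-DQA1 was lower, at −6.38 ± 0.19, with 3.11 ± 0.82 CPM in KO against 262 ± 20 in WT, HLA-DRA at −4.87 ± 0.14, with 62.3 ± 15 against 1810 ± 69, and HLA-DOA at −5.90. Class II genes were lower in 12 of 14 cases, with HLA-DPA1 at −4.62 and HLA-DRB1 at −5.01, while class I genes were lower in 5 of 18 cases and higher in 1. CCL18 (−6.22), CEBPZOS (−5.70) and NLRP2 (−5.25) were again far lower in KO. Of the IFNg genes 18 of 29 were lower, with FCGR1A at −0.98 and CXCL11 at −2.62, and 9 of 31 type I interferon genes were lower, with IFIT2 at −1.78, or 19 without untreated KO of day 73. That library is not among those compared here, so its removal acts only through the fit shared by all groups. NF-kB cytokines were lower in 9 of 24 cases, with TNF at −1.67, and IL1RN was higher by 1.57. CYP27B1, which encodes the enzyme that activates vitamin D, was higher by 4.04 ± 0.34, at 39.6 ± 14 against 2.30 ± 0.76 CPM. HSPB7 (4.03), FCRLA (3.62), NDRG4 (3.30), ADAMDEC1 (3.28), MYH14 (3.16) and PTPN13 (3.07) were also higher. Cholesterol synthesis genes were higher in 20 of 25 cases and glycolysis genes in 15 of 26, with PKM at 0.78, while LXR targets went both ways, 6 of 14 higher, with APOE at 0.63, and 3 lower, with PLTP at −0.92. Lysosome genes were lower in 20 of 33 cases, with CTSA at −0.82, scavenger receptor genes in 10 of 20, with FCGR3A at −1.52, and fibroblast markers in 7 of 8. Adjusting over the list alone moved these counts by at most 1 gene. In total 5003 genes differed (36.0%), 2406 higher and 2597 lower. Of 11 lists that passed camera, 4 held with an estimated correlation: MHC class II (adjusted p = 0.00119), cholesterol synthesis (0.00935), lysosome (0.043) and fibroblast markers (0.00535). The IFNg genes had adjusted p = 0.000282 in the preset test and adjusted p = 0.519 with an estimated correlation.

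Averaged over the 3 treatments, KO against WT asks how the genotypes differ in the mean of the treatments, which a single treatment can carry. CCL18 (−6.35 ± 0.08), CEBPZOS (−5.51), TRIM4 (−5.50), HLA-DQA1 (−5.50), HLA-DRA (−5.38), HLA-DRB1 (−5.10) and NLRP2 (−5.04) were among the lowest in KO, and HSPB7 (3.97 ± 0.12), FCRLA (3.80), PARM1 (3.45), MYEOV (3.17), PTPN13 (3.14), COL11A2 (3.13), NDRG4 (3.07) and PRSS22 (3.03) were highest. GPNMB was lower, at −3.47 ± 0.04 and C2 at −1.87. Cholesterol synthesis genes were higher in 23 of 25 cases and lower in 2, with MSMO1 at 2.15. Class II genes were lower in 13 of 14 cases, and all 31 type I interferon genes were lower, with OAS3 at −2.33 and MX1 at −2.22. By treatment, 31 of them passed as lower with LPS, 5 untreated and 9 with IFNg, or 31, 22 and 19 without untreated KO of day 73. With untreated WT of day 63 left out as well these were 31, 16 and 19. Both libraries are untreated, so they enter the LPS and IFNg counts only through the fit shared by all groups. Stress response genes moved both ways, 10 higher and 5 lower, with CALR at 0.46 and SESN2 at −0.69. Oxidative defence genes were lower in 10 of 22 cases, with FTL at −0.61. Astrocyte markers, looked at because the cells had grown on astrocyte feeders, had 2 of 6 higher and 2 lower, with GJA1 at 2.59 and GFAP at −1.46. Neuron markers gave SYT1 at 1.56 and MAP2 at −0.62, and the tested blood progenitor gene KIT stood at −0.73. The erythroid gene HBA1 was lower, at −0.20. Pluripotent markers SOX2 and DNMT3B and the endothelial gene VWF showed no change that passed, and no megakaryocyte, mast cell or granulocyte precursor marker had enough counts to test. Adjusted over the list alone, these counts moved by at most 1 gene. Genes that differed numbered 7896 (56.9%), 3879 higher and 4017 lower. The fit has no term for genotype and day together, so the 3 libraries of a genotype on a day count as separate replicates. Adjusted p-values of this averaged comparison can therefore be too small. With genotype labels exchanged so that all same-day pairs were parted, up to 2846 genes still passed. MHC class II (adjusted p = 0.00446), cholesterol synthesis (0.00896), lysosome (0.0314) and fibroblast markers (0.00638) held with an estimated correlation out of 14 lists that passed camera. For type I interferon genes the list had adjusted p = 3.31e-11 in the preset test and adjusted p = 0.319 with an estimated correlation. In the migration list the median was 0.27 and the mean −0.18, and camera leaned up without passing (adjusted p = 0.747).

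**Figure D3:**
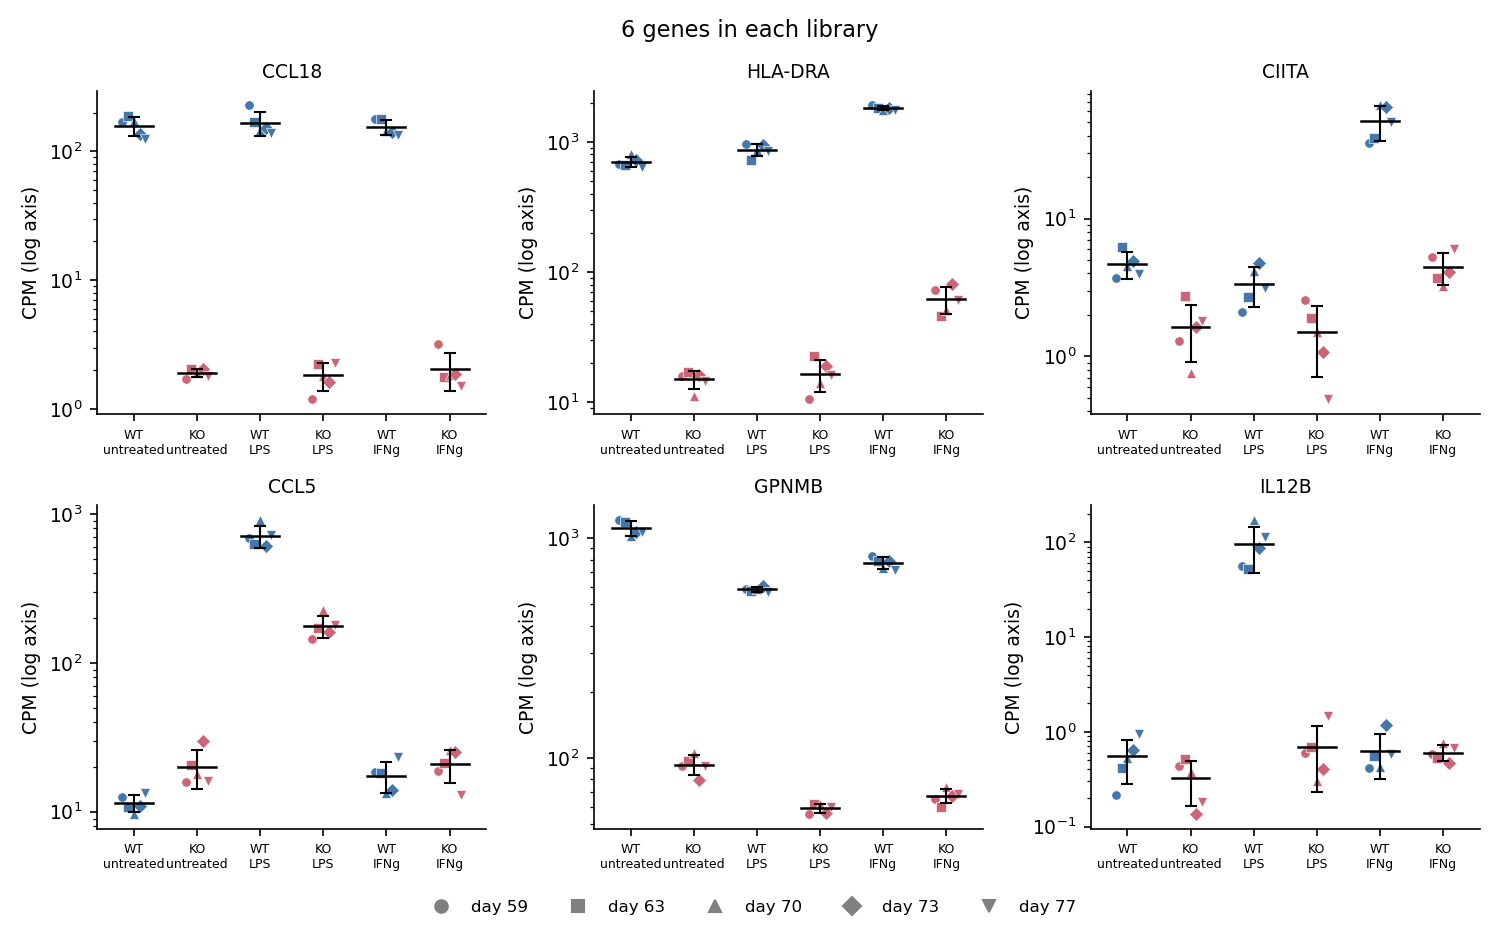
Level in CPM on a log axis of CCL18, HLA-DRA, CIITA, CCL5, GPNMB and IL12B in each of the 30 libraries, WT in blue and KO in red, with marker shape for the day, a line at the group mean and bars of ± SD. CCL18 averages 158 CPM in untreated WT and 1.90 CPM in untreated KO, and IL12B with LPS averages 96.3 CPM in WT and 0.690 CPM in KO.

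The difference of the LPS response between KO and WT asks whether the knockout changes what LPS does, apart from the resting difference. NF-kB and MHC class I genes rose less in KO. Interferon genes also rose less and homeostatic genes fell less gene by gene, but these lists did not hold with an estimated correlation (adjusted p = 0.105 for type I interferon, adjusted p = 0.0628 for IFNg genes and adjusted p = 0.156 for homeostatic genes). The difference was −6.47 ± 1.0 for ISG20, −6.42 ± 1.13 for IDO1 and −6.35 ± 0.85 for IL12B. CXCL11 (−5.84), CXCL10 (−5.40), CCL15 (−5.33), MT1M (−5.31) and RSAD2 (−5.24) came next. Type I interferon genes rose less in 30 of 31 cases, with USP18 at −4.02 and IFIH1 at −2.67, and in 29 of 31 without untreated KO of day 73. NF-kB cytokines rose less in 19 of 24 cases, 20 adjusted over the list alone, with CCL5 at −2.80, PTGS2 at −3.34 and IL1B at −2.71. Feedback genes rose less in 16 of 22 cases, 20 adjusted over the list alone, with TRAF1 at −3.60, NFKB2 at −2.23 and TNFAIP3 at −2.16. IFNg genes rose less in 24 of 29 cases, with GBP1 at −4.33, and class I genes in 15 of 18, with PSME2 at −2.02 and HLA-B at −1.04. Glycolysis genes rose less in 19 of 26 cases. Homeostatic genes fell less in KO in 11 of 19 cases, with GPR34 at 2.14 and MEF2C at 1.1, and IGF1 differed by 3.05 ± 0.27. IGF1 stood at 9.44 ± 2.8 CPM in untreated KO against 129 ± 21 in untreated WT, so the KO fall started from a lower level. VCAN (2.76), JAML (2.76), RASL11B (2.55), CCL13 (2.54), CD180 (2.44), DOK2 (2.38) and KCNJ5 (2.31) also had positive differences. For RASL11B and CD180, which fell with LPS in WT, this was a smaller fall in KO. Monocyte markers rose more in 5 of 7 cases, with S100A9 at 1.27. The other counts differed by at most 2 genes when adjusted over the list alone. A difference passed in 2840 genes (20.5%), 1504 higher and 1336 lower. Of 10 lists that passed camera, 3 held with an estimated correlation: both NF-kB lists (adjusted p = 0.00822 and 0.00295) and MHC class I (0.00679). In the preset test the type I interferon list had adjusted p = 1.95e-25, the IFNg genes adjusted p = 2.08e-21 and the homeostatic genes adjusted p = 1.97e-05. Across the 200 genes with the largest mean rise in both genotypes the median rise was 3.81 in WT and 2.04 in KO, and the median difference was −1.75 (p = 3.53e-46 by camera, and 1.17e-05 with an estimated correlation). Of these 122 passed as weaker and 1 as stronger. For the 200 genes with the largest mean fall the medians were −2.38 and −1.27, and the median difference was 1.12 (p = 5.42e-27, and 7.75e-05 with an estimated correlation).

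**Figure D4:**
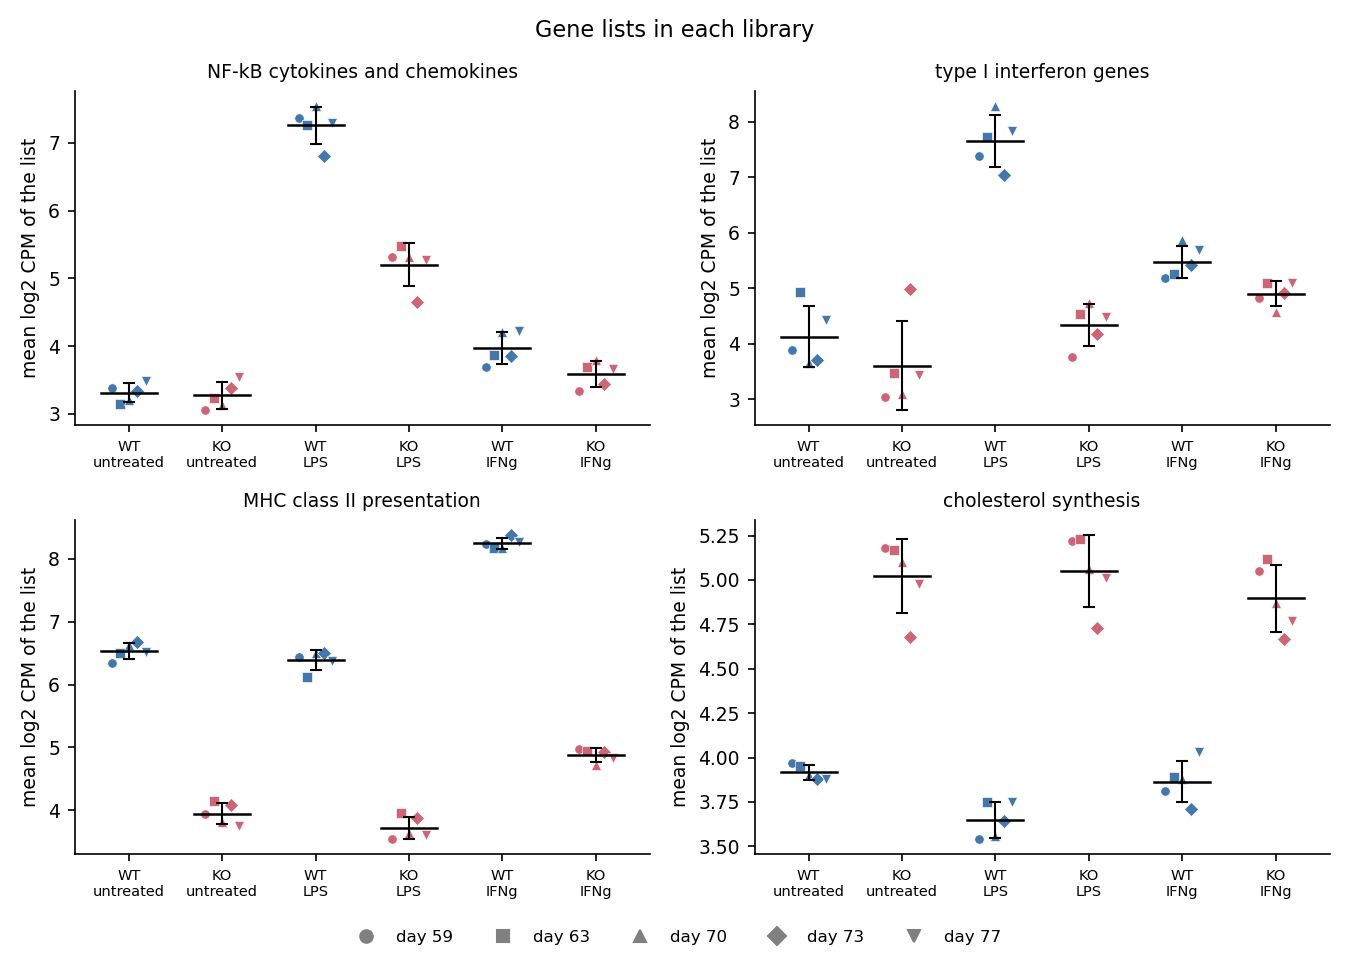
Mean log2 CPM of the NF-kB cytokines, type I interferon, MHC class II and cholesterol synthesis lists in each of the 30 libraries by group, WT in blue and KO in red, with marker shape for the day and mean ± SD. The untreated KO library of day 73 stands at 4.99 for type I interferon genes, above the other untreated KO libraries at 3.03 to 3.48.

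The difference of the IFNg response between KO and WT asks the same for the cytokine. Few genes passed, and class II genes were prominent among them. Responses were lower in KO for HLA-DQA2 (−2.88), HLA-DOA (−2.55), HLA-DQB1 (−2.46), CIITA (−1.99), ASCL2 (−1.66), HLA-DQA1 (−1.58), CALHM6 (−1.52) and ELAVL4 (−1.5). CIITA went from 4.67 ± 1.0 to 51.1 ± 14 CPM in WT and from 1.64 ± 0.73 to 4.46 ± 1.2 CPM in KO. Class II genes rose less in 8 of 14 cases and more in 1, with 9 and 2 adjusted over the list alone. HLA-DRA did not rise less: it went from 702 ± 65 to 1810 ± 69 CPM in WT and from 15 ± 2.3 to 62.3 ± 15 CPM in KO. Class I genes rose less in 3 of 18 cases, 8 adjusted over the list alone, with PSME2 at −0.84. Proliferation genes fell more in 3 of 25 cases, 7 adjusted over the list alone, with RRM2 at −1.48 and NUSAP1 at −1.24. C1S (1.96), LYPD1 (1.91), PRSS23 (1.77), IGF1 (1.60), SLC18B1 (1.58), PITPNM3 (1.49), SLC7A11 (1.46) and PAQR5 (1.44) had positive differences. Such a difference can be a WT fall that KO lacked. IGF1 went from 129 ± 21 to 43.6 ± 11 CPM in WT and from 9.44 ± 2.8 to 9.59 ± 0.31 CPM in KO. LYPD1 (−1.85), PITPNM3 (−2.19) and SLC18B1 (−1.66) also fell with IFNg in WT. For type I interferon genes the median of −0.23 became 0.49 without untreated KO of day 73, −0.45 without untreated WT of day 63 and 0.28 without both. The difference passed in 308 genes (2.22%), 155 higher and 153 lower, in 205 without KO with IFNg of day 59 and in 73 to 154 without a whole day. It passed in 131 genes without the day block and in 496 without the filter on low counts, and by limma-trend 38.4% of the genes that passed were higher, against 50.3%. Of 8 lists that passed camera only MHC class II held with an estimated correlation (adjusted p = 3.58e-08, and 0.0242). Proliferation genes had adjusted p = 1.85e-07, and adjusted p = 0.127 with an estimated correlation. The 200 genes most raised by IFNg rose by a median of 2.21 in WT and 1.99 in KO, with a median difference of −0.33 (p = 1.15e-07 by camera, and 0.179 with an estimated correlation). Without untreated KO of day 73 that difference was −0.07. For the 200 most lowered genes the medians were −1.23 and −1.1 and the median difference 0.15, which did not pass camera. Across genes, which are not independent replicates, the slope of the KO on the WT response was 0.474 for LPS over 6431 genes and 0.864 for IFNg over 4044 genes. The correlations across these genes were 0.786 for LPS and 0.879 for IFNg. Scatter in the WT response lowers a slope, so neither slope is a ratio of response sizes.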

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

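The tests of fewer responding cells, of reads shared between HLA paralogs, of the class II transactivator, of a deletion around PILRA and of fits without single libraries were chosen only after the result was seen. Among 246 groups of 5 libraries 13 had a library far from the other 4, and chance gives about 1 in 20 such groups, or 12 here. In KO with IFNg these were CCL18 at 3.20 CPM on day 59 (others 1.51 to 1.88), CD74 at 376 on day 73 (265 to 277) and TNF at 9.40 on day 77 (4.07 to 4.95). In WT with LPS they were LILRB1 at 453 CPM on day 73 (228 to 257) and CXCL10 at 1640 on day 70 (112 to 441). In WT with IFNg they were IL12B at 1.18 CPM on day 73 (0.416 to 0.58), NFKBIA at 290 on day 77 (167 to 202) and TLR4 at 250 on day 59 (208 to 220), and IDO1 stood at 4.13 CPM in KO with LPS on day 63 (2.01 to 2.60). List means on the log2 CPM scale were low for NF-kB cytokines in KO with LPS of day 73, at 4.65 (5.27 to 5.48), for IFNg genes in KO with LPS of day 59, at 3.75 (4.01 to 4.09), and for proliferation in WT with IFNg of day 73, at 2.18 (2.62 to 2.77). The type I interferon mean was high in untreated KO of day 73, at 4.99 (3.03 to 3.48).

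Responses differed between the genotypes by tests of the difference itself. The LPS response differed in 2840 genes and the IFNg response in 308. Medians of the difference were −1.75 for the LPS-induced genes and 1.12 for the LPS-repressed genes. For the IFNg-induced genes the median was −0.33, which passed camera with the preset correlation but not with an estimated correlation, and was −0.07 without untreated KO of day 73. With LPS they were −2.03 for NF-kB cytokines, −1.17 for NF-kB feedback genes and −1.04 for MHC class I genes, and with IFNg −0.43 for MHC class II genes. Splits of the libraries by genotype and day were fitted with each genotype and day as a block, in place of the day alone. Real values there differ from those above for that reason. In the LPS difference the splits gave 3102 genes for the real split and 156 for the highest other. For the IFNg difference these were 448 and 2, and each real count was reached in 1 of 60 splits. Only 10 of the 60 splits, the real one included, part all same-day pairs. With the days kept as pairs these are too few for a share under 0.05, so the splits alone cannot exclude chance. For the LPS-induced genes the real split gave −1.66 and the highest other −1.34, and for the LPS-repressed genes 1.1 and 0.75, each in 1 of 60, under the same limit. The IFNg-induced genes gave −0.32 for the real split and −0.51 for another, with 16 of 60 splits as large, and the IFNg-repressed genes 0.16 and 0.22, with 6 of 60. For these 2 chance cannot be excluded with all 60 splits either.

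The smaller LPS response in KO was weighed first. Libraries thinned to 3.87 M counts still gave −1.83 over the LPS-induced genes, which argues against depth, and these genes stood at −0.14 in untreated KO against WT, which argues against an early rise. KO kept a median of 2.95% of the WT rise of type I interferon genes and 22.2% of the NF-kB genes (permutation p = 1e-04 across genes, which are not independent replicates), and 5 of 7 monocyte markers rose more in KO, so a single lower share of responding cells is argued against. Without untreated KO of day 73 the share was 4.8%, and 2.78% without untreated WT of day 63, and secreted interferon may amplify the gap, which weakens the type I share taken alone. Lower levels of the LPS receptor genes cannot be told apart from an effect of PILRA, since TLR4 stood at −0.82 and LY96 at −0.51 in the same untreated KO cells and CD14 at −0.16 (adjusted p = 0.642).

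Lower MHC class II in KO was weighed second. Sharing of reads between HLA paralogs is argued against by CD74, which has no such paralog and stood at −1.91, and CIITA at −2.05. Dendritic cells in WT alone are argued against by a median of 1.12 over their markers, which were higher in KO for CD1A (2.58), CD1C (1.87) and CLEC10A (2.02), lower for CCR7 (−2.93) and LAMP3 (−1.40). A lower level of the transactivator may account for part of the fall: the 11 genes that are HLA-D genes or CD74 had a median of −4.15 (−5.50 to −0.13), against −0.23 for CTSS and IFI30. Yet CIITA stood at 4.46 ± 1.2 CPM in KO with IFNg and at 4.67 ± 1.0 in untreated WT, while HLA-DRA stood at 62.3 ± 15 and 702 ± 65. The class II list mean in these groups was 4.88 ± 0.11 and 6.53 ± 0.13 on the log2 CPM scale. These values argue against the CIITA transcript level as the whole cause. Whether PILRA or another difference between the cells sets CIITA was not tested.

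The wide difference between the genotypes was weighed last. Of 12 genes near 0 in KO only (at most 5% of WT in each treatment, with at least 10 CPM in WT) 1 lay within 5 Mb of PILRA, TRIM4, and the 94 tested genes there had a median of 0.04, which argues against a deletion as the whole cause. No chromosome arm of 41 stood further from 0 than 10p at −0.18, against a gained or lost arm. Matrix genes had a median of −1.22, with CALD1 at −3.28 and SPARC at −1.10, so mesenchymal cells in the WT cultures may explain that part, though FN1 (2.04) and COL6A1 (2.33) were higher in KO. Differences between the genotypes other than PILRA stay open and were not tested.

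Other splits gave far fewer genes than the real split in each pairwise comparison, in 1 of 100 drawn splits each. Only 13 of the 100, the real one included, part all same-day pairs, too few for a share under 0.05 with the days kept. The splits alone therefore cannot exclude chance. These pairwise fits held only the groups compared, so the real counts differ from those of the main fit. Real and highest other counts were 5529 and 0 for LPS in WT, 3213 and 7 for IFNg in WT, 2640 and 82 for LPS in KO, 2224 and 17 for IFNg in KO, 4673 and 6 for untreated KO against WT, 5101 and 19 with LPS, 4256 and 0 with IFNg, and 4851 and 10 for LPS against IFNg in WT. Averaged over treatments the real split gave 7896 and the highest other 5637, in 1 of 60 splits by genotype and day, of which 10 part all same-day pairs. That other split leaves some same-day pairs together, and the highest other count among splits that part all same-day pairs was 2846.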

How the results depend on the processing

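Redrawn rounding and the fits without the untreated KO library of day 73, alone or with WT with LPS of day 70 or untreated WT of day 63, and without the latter alone, were chosen only after the result was seen. DESeq2, limma-trend on the authors' values, RLE size factors, redrawn rounding and fits of only the groups compared each left all 11 gene counts within 1.5 times their value, as did the fit without the 2 libraries. Without a filter the IFNg difference gave 496 genes, and without the day block 131, against 308; leaving out a day gave 73 to 154 and leaving out a library 205 to 318. IFNg in KO gave 1396 to 2101 genes without a day and 1731 to 2161 without a library, against 2211. Day ranges of the other counts were 2121 to 2454 for the LPS difference, 5600 to 5881 for LPS in WT, 2227 to 2548 for LPS in KO and 7145 to 7414 for KO against WT averaged. Fewer libraries leave fewer degrees of freedom; the cause was not tested further. The IFNg-repressed median was 0.18 with 500 genes and 0.16 with only the groups compared, both past the threshold, and 0.06 to 0.25 leaving out a day or a library, past the threshold in 13 of these 25. The IFNg-induced median (−0.33) had p = 0.179 with an estimated correlation, ran from −0.52 without day 63 to 0.01 without day 73, where it reversed, and was −0.07 without untreated KO of day 73 and −0.05 without the 2 libraries. The type I interferon list in the IFNg difference turned from −0.23 to 0.50 without day 73 and was −0.62 without day 63. An estimated correlation left 46 list tests of 134. By fry the migration list averaged over treatments reversed, with a median of 0.27 and a mean of −0.18. The cause was not tested for these. Without a filter the share of higher genes went from 49.2% to 61% in untreated KO against WT, and from 48.1% to 59.6% with IFNg, and the averaged comparison gave 4715 higher and 3167 lower genes. In the IFNg difference the share of higher genes went from 50.3% to 38.4% by limma-trend and to 39.2% without WT with IFNg of day 59. Of the named-gene results DESeq2 kept 1144 past the threshold and weakened 5, and fits without the day block kept 1090 and weakened 59. The rise of PILRA with LPS in KO (0.70) was 0.66 without day 63, 0.59 without day 73 and 0.69 with no day block, and did not pass in these 3. A 1.5-fold difference of the LPS response was recovered in 58.2% of simulated genes with a mean of at least 10 CPM at this depth, so smaller differences are missed more often.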

Other observations

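Tests here of the adaptor genes were chosen only after the result was seen. Genes of the LPS and interferon pathways gave values outside the comparisons above. In untreated KO the TRIF adaptor gene TICAM1, which carries the interferon arm of Toll-like receptor 4, stood at 2.25 CPM against 7.53 in WT (−1.71, adjusted p = 1.21e-05), and the shared adaptor gene MYD88 at 35.6 against 60.3 CPM (−0.74, adjusted p = 3.59e-05). The interferon receptor gene IFNAR2 stood at −0.38 and IRF9 at −0.68, while TRAF6 was higher by 0.40. CD14 went the other way, with 792 CPM in WT and 1370 CPM in KO with LPS.

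Matrix genes moved apart in KO. COL6A1 stood at 222 CPM in untreated KO against 43.3 in WT, COL6A2 at 36.7 against 7.66 and FN1 at 909 against 248, while POSTN, CCN2 and IGFBP7 stood at −4.32, −4.53 and −3.14 averaged over treatments. POSTN, CCN2 and IGFBP7 were low even in untreated WT, at 3.41, 4.05 and 9.41 CPM, against 0.129, 0.151 and 0.741 CPM in untreated KO. SPP1, the most abundant of the genes followed per library, stood at 41900 CPM in untreated KO and 39300 in untreated WT.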
